A study of Rattus norvegicus with 6 samples.

How the data were processed

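RNA was sequenced from 3 libraries of RCS cells, a cell line grown from a rat chondrosarcoma, and 3 libraries of rat rib tissue. Groups and replicate numbers came from the sample titles, and the series design text calls the replicates biological without saying which cultures or animals they came from. The p-values therefore measure the spread between these libraries only.

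The values deposited by the authors were log2 values in 1 table of 27217 genes for the 6 libraries. Their scale was worked out from the values. In each library, 2 to the power of the 5 most frequent low values fell on multiples of 1 step, a step common to many genes, which division by gene length would not leave. The values were therefore read as log2 of a read count divided by 1 factor per library, called a normalized count here, and not as counts per length, although the deposited table's name carries that unit. A normalized count of 1 or less was listed as 0. CASAVA 1.8, DESeq and the genome build rn5 are named in the submitters' processing notes with no role given. The aligner, the counting rule, the use of strand and the treatment of reads with several matches are not given in the sources used here. Of the values of at most 10 reads, 38.6% to 54.5% per library lay within 0.01 of a whole read, where chance gives 2%, and the others did not, so whole reads were not recovered for nearly all genes and no count model was used. Values were not divided by gene length, so levels of different genes are not molar amounts.

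Depth was estimated as the sum of normalized counts divided by the step. It was 8310000, 8520000 and 6000000 reads on genes in RCS cells replicates 1 to 3 and 7490000, 5320000 and 5580000 in rib tissue replicates 1 to 3. One read was worth 0.544, 0.519 and 0.709 normalized counts in the RCS libraries and 0.758, 1.03 and 1.0 in the rib libraries. The smallest listed normalized count was 1.00 to 1.02 in the 6 libraries, so a gene listed at 0 was taken to have a normalized count of 1 at most. That is up to 1.84, 1.93 and 1.41 reads in RCS cells replicates 1 to 3 and up to 1.32, 0.975 and 1.0 reads in rib tissue replicates 1 to 3. No library pair was identical (0 pairs).

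Gene symbols are those of the table. Entrez identifiers in the table were looked up in NCBI RefSeq gene names of the assembly GRCr8, used for names only, and 17258 of 17717 matched. Of 488 names in 20 gene lists, 455 matched by symbol, 16 through Entrez identifiers and 3 after a change of capitals, and 14 had no match. Where several table entries carried a name, the one with the highest mean was used.

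Normalized counts were tested as log2(normalized count + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend, two-sided), on 16809 genes with a normalized count of at least 1 in at least 3 of the 6 libraries. Differences are RCS cells minus rib tissue. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and a 2-fold limit was applied as a second count. Fold changes are on the log2(normalized count + 1) scale, which understates changes of low genes, and are left out where a group's mean was under 10 normalized counts. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 20 lists. The lists were the SOX trio and skeletal transcription factors, cartilage matrix, hypertrophic chondrocyte, osteoblast and bone matrix, osteoclast, fibroblast and perichondrium, skeletal muscle, erythroid, myeloid, lymphoid, endothelial, adipocyte, Schwann and nerve, cell cycle, cell cycle inhibitors and tumour suppressors, glycosaminoglycan synthesis and sulfation, collagen processing and secretion, Hox, growth factor signalling of the growth plate, and glycolysis and hypoxia response. They share 1 gene (Ibsp, in the hypertrophic and osteoblast lists).

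The groups, lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. The plan allowed for either counts or normalized values per length. The values were neither, and the branch for normalized values was used. Named genes were Sox9, Sox5 and Sox6, the 5 largest differences in each direction among called genes without overlap between the groups and with at least 10 CPM (normalized counts scaled to the same library total) in the higher group (symbols starting with LOC, RGD, Mir or Snor and genes named only by an identifier left out), the 2 members of each list with the highest mean, and for cartilage matrix and hypertrophic chondrocyte also the 2 most raised and 2 most lowered called members. This gave 59 genes, of which 1 is not reported here, and 20 more were chosen after their values were seen. These are Acan, Hapln1, Ihh, Mmp13, Runx2, Sp7, Sox8, Prrx1, Cdkn2a, Cdkn1c, Sox2, Shox2, Barx1, Nkx3-2 and the Hox genes Hoxb7, Hoxb8, Hoxc10, Hoxa11, Hoxa13 and Hoxb13.

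The alternatives fixed beforehand were quantile normalization, scaling to the library median, no filter, a filter of 5 CPM, a pseudocount of 0.1, array weights, the replicate number as a block, and each library left out in turn with the same genes tested. Log2 values as deposited, cyclic loess normalization and voom weights on estimated reads were added after the data were seen.

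The limma script was tested on simulated data for RCS cells against rib tissue, 3 against 3, over 16923 genes with a dispersion of 0.02. It called 16.4% of 67 genes changed by 1.5-fold, 71.6% of 67 changed by 2-fold and 87.9% of 66 changed by 4-fold, all with the right sign, and 3 of 120 calls (2.5%) were false. A shifted list gave a camera p of 6.71e-85, and 0 of 20 unshifted lists were called. Simulated genes were drawn independently, with the same dispersion in both groups and few genes changed. In the data, list members were correlated (estimated at up to 0.768, adipocyte) and the median SD was 0.0888 in RCS cells and 0.16 in rib tissue. These rates therefore need not hold for the data. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.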

Results

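Gene expression was measured by RNA sequencing in 3 libraries of RCS cells, a chondrocyte-like line from a rat chondrosarcoma, and in 3 libraries of rat rib tissue, pieces of which can hold cartilage, bone, muscle and other tissues. The estimated depth was 6000000 to 8520000 reads on genes in RCS cells and 5320000 to 7490000 in rib tissue. Levels are given as log2(normalized count + 1), as mean ± SD with n = 3 libraries, and differences as RCS cells minus rib tissue with their SE. Of 27217 genes, 13838 were listed above 0 in all 3 RCS libraries and 16142 in all 3 rib libraries. The 10 most abundant genes took 1.79% to 2.32% of an RCS library and 5.07% to 6.46% of a rib library. The 122 ribosomal protein entries took 0.621% to 0.725% of an RCS library and 0.363% to 0.455% of a rib library. Gapdh stood at 462 to 796 normalized counts over the 6 libraries and Fat1 at 6123 to 8866. Whether values of abundant genes were flattened in all libraries was not tested, so the sizes of their differences hold on this scale only.

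The comparison asks how the transcriptome of RCS cells, which the series title places in work on SOX9, SOX5 and SOX6, differs from that of rib tissue. Among genes with a symbol that met the rule for named genes, those with the largest differences were high in one group and near or at 0 in the other. Rib tissue was higher in Smoc2, a secreted matricellular protein gene (ENSRNOG00000014166, 0.47 ± 0.81 in RCS cells against 12.78 ± 0.49), the muscle myosin gene Myh2 (0.47 ± 0.81 against 11.97 ± 0.35), the microfibril gene Fbn2 (11.57 ± 0.19 in rib tissue), the growth factor gene Igf1 (11.34 ± 0.07) and the microRNA gene rno-mir-127 (11.97 ± 0.16). Fbn2, Igf1 and rno-mir-127 were listed at 0 in every RCS library. Reads of rno-mir-127 were not told apart from those of longer transcripts that overlap it. RCS cells were higher in Tex101 (10.15 ± 0.20 against 1.65 ± 0.35) and Tex11 (7.97 ± 0.14), both best known from the testis, and in the transcription factor gene Isl1 (7.77 ± 0.11). Rpl39l, a ribosomal protein gene of a family with near-identical copies, stood at 7.39 ± 0.09 in RCS cells and is uncertain for that reason. Tex11, Isl1 and Rpl39l were listed at 0 in every rib library.

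In limma with Benjamini-Hochberg adjustment, 5536 genes were higher in RCS cells and 7324 in rib tissue, 76.5% of 16809 tested. At least 2-fold, 2369 were higher in RCS cells and 5571 in rib tissue. The groups did not overlap at 13268 genes (78.9%, where chance gives 10%). The first principal component held 95.2% of the variance, and libraries correlated across genes at 0.97 to 0.99 within a group and 0.65 to 0.69 between groups. Of the called genes, 43.0% were higher in RCS cells, against 61.9% under quantile normalization (8000 higher, 4924 lower), 53.3% under median scaling (7121 and 6248) and 50.1% under cyclic loess (6242 and 6206). Quantile normalization moved the median gene by 0.53 and median scaling by 0.29 towards RCS cells, so small differences are relative to the scaling.

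The SOX trio, the transcription factors that drive chondrocyte differentiation, stood at similar high levels in both groups. Sox9 (ENSRNOG00000002607) was at 9.95 ± 0.22 in RCS cells and 10.29 ± 0.27 in rib tissue, a difference of -0.34 (SE 0.16, 95% interval -0.70 to 0.02). Sox5 (listed as Sox5l1, ENSRNOG00000027869) was at 9.63 ± 0.01 and 9.36 ± 0.45, a difference of 0.27 (SE 0.19, interval -0.18 to 0.72). Sox6 (ENSRNOG00000020514) was lower in RCS cells, at 10.12 ± 0.08 against 10.55 ± 0.24, a difference of -0.43 (SE 0.12). The limma adjusted p (Benjamini-Hochberg) was 0.0772 for Sox9, 0.232 for Sox5 and 0.0115 for Sox6. The Sox6 call was lost under quantile normalization and median scaling (both -0.14), Sox9 was called without rib tissue replicate 2 (-0.48), and Sox5 was called without rib tissue replicate 3 (0.53), under median scaling (0.56) and with array weights (0.40). Over 16 alternatives the limma adjusted p, by Benjamini-Hochberg, ran from 0.025 to 0.824 for Sox9, 0.000459 to 0.614 for Sox5 and 0.00945 to 0.396 for Sox6.

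Of 27 tested SOX and skeletal transcription factor genes, 8 were higher in RCS cells, 14 lower and 5 neither (9 higher and 14 lower adjusted over the list alone), and camera gave a limma adjusted p (Benjamini-Hochberg) of 0.519 for the list. Sox8, a relative of Sox9, was at 9.68 ± 0.14 in RCS cells and 7.39 ± 0.14 in rib tissue, 4.89-fold higher. Prrx1, a limb and perichondrium mesenchyme factor, was at 10.37 ± 0.21 in rib tissue and listed at 0 in every RCS library. Runx2, the factor of chondrocyte hypertrophy and bone formation, was at 10.32 ± 0.16 and 10.08 ± 0.08 and was called only in alternatives, higher under quantile normalization (0.51), median scaling (0.53), cyclic loess (0.32) and array weights (0.25) and without RCS cells replicate 3 (0.30). The ubiquitin ligase gene Wwp2 was at 10.95 in RCS cells and 11.00 in rib tissue, a difference of -0.04 that turned positive under quantile normalization (0.52, called), median scaling (0.25) and cyclic loess (0.18).

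Cartilage matrix genes were abundant in both groups and split in direction. Col2a1, the main collagen of cartilage (ENSRNOG00000022282), was at 13.76 ± 0.33 in RCS cells and 16.37 ± 0.54 in rib tissue, 6.13-fold higher in rib tissue (difference -2.62, SE 0.32). The matrix protein genes Matn1 (12.31 ± 0.18 against 10.61 ± 0.27, 3.25-fold, SE 0.15 log2) and Prelp (12.23 ± 0.19 against 10.64 ± 0.16, 3.01-fold, SE 0.13 log2) were higher in RCS cells. Cytl1, listed at 0 in every RCS library, was at 9.57 ± 0.26 in rib tissue, and Cilp2 was at 1.41 ± 0.31 against 10.73 ± 0.19. Acan, the main proteoglycan, was at 13.88 ± 0.29 in RCS cells and 13.62 ± 0.24 in rib tissue (0.26, interval -0.20 to 0.72), and Hapln1, its link protein, at 12.27 ± 0.08 and 12.31 ± 0.33 (-0.04, interval -0.43 to 0.34).

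Of 28 cartilage matrix genes, 5 were higher in RCS cells, 12 lower and 11 neither (4 higher and 12 lower adjusted over the list alone), and 15 lay within 2-fold. The limma adjusted p (Benjamini-Hochberg) was 0.000102 for Col2a1, 1.65e-05 for Matn1, 8.55e-06 for Prelp, 0.459 for Col9a1 and, by camera, 0.247 for the list. Under median scaling 5 were higher and 11 lower. Under quantile normalization 14 were higher and 9 lower, and under cyclic loess 10 higher and 12 lower, and under these 2 settings Acan (2.06 and 1.07) and Hapln1 (1.04 and 0.45) were called higher in RCS cells and Col9a1 turned from -0.19 to 1.57 and 0.68. Col2a1 kept its direction at -0.60 and -1.51, while Matn1 moved from 1.70 to 2.59 and Prelp from 1.59 to 2.39 under quantile normalization. The count of higher members was 2 without RCS cells replicate 2, rib tissue replicate 1 or rib tissue replicate 2, and 3 without RCS cells replicate 1.

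**Figure D1:**
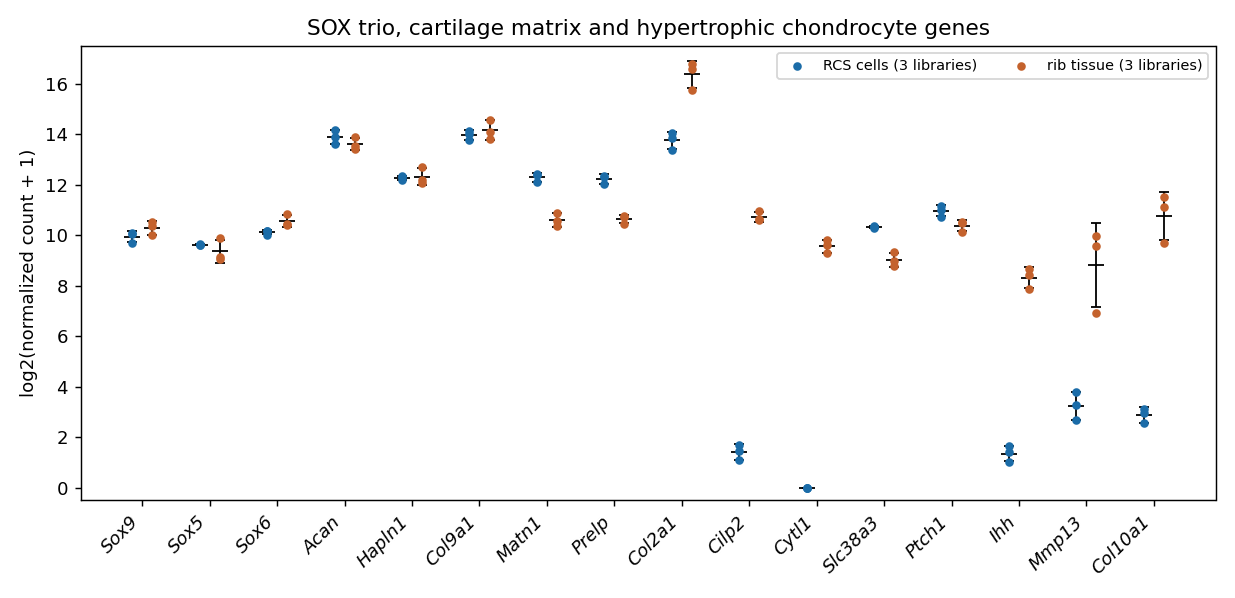
Levels of the SOX trio, cartilage matrix and hypertrophic chondrocyte genes as log2(normalized count + 1), with 1 point per library and bars for the mean and SD of 3 libraries in RCS cells (blue) and rib tissue (orange). Sox9 lies at 9.95 and 10.29, while Col10a1 lies at 2.89 in RCS cells and 10.76 in rib tissue.

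Genes of hypertrophic chondrocytes, the enlarged cells that precede bone, were split, with some at low levels in RCS cells and high levels in rib tissue. Col10a1, the collagen of that zone, was at 2.89 ± 0.30 in RCS cells and 10.76 ± 0.95 in rib tissue. The signal gene Ihh was at 1.36 ± 0.31 against 8.32 ± 0.41 and the collagenase gene Mmp13 at 3.25 ± 0.55 against 8.81 ± 1.66, a difference of -5.56 that was -6.51 without rib tissue replicate 3. Adamtsl1 was listed at 0 in every RCS library and at 7.80 ± 0.30 in rib tissue. The hedgehog receptor gene Ptch1 was higher in RCS cells (10.97 ± 0.22 against 10.39 ± 0.22, 1.495-fold), as was the amino acid transporter gene Slc38a3 (10.34 ± 0.04 against 9.03 ± 0.27, 2.48-fold). Of 15 genes, 3 were higher in RCS cells, 8 lower and 4 neither, with a camera adjusted p (limma, Benjamini-Hochberg) of 0.147, and the list was called lower under quantile normalization (median -0.42). Sgms2 was at 10.22 and 10.40, a difference of -0.18 that turned positive under quantile normalization and median scaling (both 0.11), and was called lower with array weights (-0.23), a pseudocount of 0.1 (-0.18) and without rib tissue replicate 3 (-0.20).

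Genes that build and sulfate glycosaminoglycan chains split between the groups. Of 28, 8 were higher in RCS cells, 15 lower and 5 neither (camera adjusted p 0.787, limma with Benjamini-Hochberg), with 13 higher and 10 lower under quantile normalization. Xylt1, which starts the chains, was 2.74-fold higher in rib tissue, and the sulfotransferase gene Chst11 differed by 0.16 without passing the test, called higher in RCS cells under quantile normalization (0.99), cyclic loess (0.50) and without rib tissue replicate 3 (0.35). Of 28 genes of collagen processing and secretion, 4 were higher in RCS cells, 17 lower and 7 neither (camera adjusted p 0.0763, limma with Benjamini-Hochberg). The list was called lower under quantile normalization (median -0.37, with 10 genes higher), cyclic loess (-0.53, with 7 higher) and the filter of 5 CPM (-0.51), and 8 genes were higher and 13 lower under median scaling. P4hb, a subunit of prolyl hydroxylase, was 1.45-fold higher in RCS cells (log2 0.53, and 1.385 under quantile normalization), and the collagen chaperone gene Serpinh1 differed by 0.14 without passing the test, called higher under quantile normalization (0.91), median scaling (0.44) and cyclic loess (0.46).

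Markers of the other cell types in a rib piece were far lower in RCS cells. All 27 skeletal muscle genes were lower, among them the embryonic myosin gene Myh3 (1.45 ± 0.70 against 12.65 ± 0.34) and nebulin, Neb (2.78 ± 0.41 against 12.82 ± 0.33). Of 21 fibroblast and perichondrium genes, 20 were lower and 1 neither, with Col3a1 909-fold higher in rib tissue (3.62 ± 0.43 against 13.45 ± 0.34) and Col5a1 246-fold (4.98 ± 0.06 against 12.92 ± 0.33). All 20 myeloid genes were lower, including the macrophage receptor genes Csf1r (40.9-fold) and Mrc1 (2.87 ± 0.76 against 9.46 ± 0.34). Of 20 endothelial genes, 19 were lower and 1 neither. Egfl7 was 1.84-fold higher in rib tissue, and Vwf differed by -0.20, turned to 0.098 under median scaling and was called without rib tissue replicate 3 (-0.40). Of 14 adipocyte genes, 13 were lower and 1 neither (12 lower and 1 higher under median scaling), and the lipid uptake genes Lpl (9.93 ± 0.50 in rib tissue) and Cd36 (8.80 ± 0.39) were listed at 0 in every RCS library. In all, 6 muscle, 5 fibroblast, 11 myeloid, 9 endothelial and 7 adipocyte genes tested were listed at 0 in every RCS library. They passed the filter through rib tissue and could not come out higher, so the filter shaped these counts. Of 26 myeloid genes in the table, 20 were tested.

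These 5 lists were lower in RCS cells by camera in limma, with Benjamini-Hochberg adjusted p of 7.33e-10 for muscle, 2.74e-08 for fibroblast, 1.94e-05 for myeloid, 1.64e-06 for endothelial and 0.00221 for adipocyte genes. The calls were lost with an estimated correlation. The limma Benjamini-Hochberg adjusted p was then 0.5 for muscle and endothelial, 0.291 for fibroblast, 0.52 for myeloid and 0.62 for adipocyte genes. The 16 other alternatives kept them, with 0.00681 (adipocyte) as the highest camera adjusted p in limma, by Benjamini-Hochberg. Marker levels differed among the rib libraries. The mean over muscle genes was 10.56, 10.49 and 9.59 in rib tissue replicates 1, 2 and 3, over erythroid genes 6.59, 5.93 and 4.85, and over adipocyte genes 7.51, 7.40 and 5.86, while cartilage matrix genes averaged 11.39, 11.16 and 11.64. Under quantile normalization the difference moved from -9.83 to -8.28 for Col3a1, from -7.94 to -6.78 for Col5a1 and from -5.36 to -4.38 for Csf1r.

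Bone, blood and nerve markers moved less evenly. Of 17 osteoblast and bone matrix genes, 11 were lower in RCS cells, 2 higher (4 under quantile normalization and cyclic loess) and 4 neither, with Col1a1 822-fold (5.05 ± 0.22 against 14.73 ± 0.61) and Col1a2 577-fold (3.87 ± 0.19 against 13.04 ± 0.66) higher in rib tissue. Sp7, the osteoblast factor, was at 8.51 ± 0.08 and 8.47 ± 0.58, a difference of 0.04 that turned to -0.13 under cyclic loess. Of 14 osteoclast genes, 10 were lower, 2 higher (4 under quantile normalization) and 2 neither. Nfatc1 was 3.33-fold higher in rib tissue, and Clcn7, a chloride channel gene, 1.27-fold higher in RCS cells. Of 13 erythroid genes, 10 were lower and 3 neither. The globin gene Hba-a1 (listed as Hba-a2, one of several near-identical copies and so uncertain) was at 8.67 ± 1.29 in rib tissue and listed at 0 in every RCS library, with a difference of -8.67 that was -8.03 without rib tissue replicate 1 and -9.32 without rib tissue replicate 3. Tmcc2 was at 8.16 in both groups, a difference of 0.00 that turned to -0.20 under cyclic loess. Of 15 Schwann and nerve genes, 12 were lower, 2 higher and 1 neither. S100b was 1.58-fold higher in rib tissue, a call lost under median scaling (-0.37), and Pmp22 differed by -0.10, turning to 0.068 under quantile normalization and 0.19 under median scaling. Of 10 lymphoid genes, 4 were higher, 3 lower and 3 neither, against 7 higher and 1 lower under cyclic loess and 6 and 1 under quantile normalization. The B-cell factor gene Ebf1 was at 8.87 ± 0.28 in rib tissue and listed at 0 in every RCS library, and Vpreb1 was 1.25-fold higher in RCS cells, a call lost under cyclic loess (0.16). Members named for a high mean need not mark the cell type of their list. S100b stood at 9.49 in RCS cells, and the lymphoid list had a median of 1.66 to 2.07 in the rib libraries. Listed at 0 in every RCS library, and so unable to come out higher, were 3 osteoblast, 6 osteoclast, 4 erythroid, 3 Schwann and 1 lymphoid genes.

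By camera in limma, the Benjamini-Hochberg adjusted p was 0.0373 for osteoblast, 0.033 for erythroid, 0.0149 for Schwann, 0.0686 for osteoclast and 0.65 for lymphoid genes. With the correlation estimated, the calls were lost, at limma Benjamini-Hochberg adjusted p = 0.62 with an estimated correlation for osteoblast and erythroid genes and 0.52 for Schwann genes. The osteoblast call was also lost with a pseudocount of 0.1 (median -6.46), with voom weights (-6.47) and without rib tissue replicate 1 or 2 (-5.09 and -5.10). The erythroid call was also lost under quantile normalization (-0.30, with 5 of 13 genes lower and 1 higher), under cyclic loess (-1.04, with 6 lower and 1 higher), with voom weights (-3.39) and without rib tissue replicate 1 (-2.48). The osteoclast list was called lower under quantile normalization (-1.90), median scaling (-3.19) and array weights (-3.28) and without rib tissue replicate 3 (-3.71), and 1 lymphoid gene in place of 3 was lower without RCS cells replicate 3. Under quantile normalization the difference moved from -9.68 to -8.245 for Col1a1 and from -9.17 to -7.74 for Col1a2. The median of the lymphoid list was 0.08 and its mean -0.60, with camera up and fry down.

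Cell cycle genes were all higher in RCS cells. Of 32, 32 were higher and 30 at least 2-fold, with the replication and mitosis gene Top2a 3.07-fold higher (11.82 ± 0.12 against 10.20 ± 0.10) and the proliferation marker Mki67 1.44-fold (11.26 ± 0.12 against 10.74 ± 0.17). Under quantile normalization the difference moved from 1.62 to 2.34 for Top2a and from 0.52 to 1.14 for Mki67. Camera in limma gave a Benjamini-Hochberg adjusted p of 6.85e-12, and adjusted p = 0.5 with an estimated correlation. Of 15 cell cycle inhibitors and tumour suppressors, 8 were higher, 6 lower and 1 neither (camera adjusted p 0.537, limma with Benjamini-Hochberg), with a median of 0.23 and a mean of -0.17, camera up and fry down. Cdkn2a, the Ink4a and Arf locus, was at 6.85 ± 0.06 in RCS cells and 1.10 ± 1.005 in rib tissue, whereas Cdkn1c, an imprinted inhibitor, was at 3.03 ± 0.05 against 9.48 ± 0.21. Nf1 (2.56-fold) and Apc (1.81-fold) were higher in rib tissue.

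Growth factor genes of the growth plate were mostly lower in RCS cells. Of 35, 26 were lower, 6 higher and 3 neither, with Igf2 770-fold higher in rib tissue (3.82 ± 0.11 against 13.41 ± 0.22). Among the 35, 8 were listed at 0 in every RCS library and could not come out higher. Fgfr3, the receptor that restrains chondrocyte growth, was 1.99-fold higher in RCS cells (11.70 ± 0.19 against 10.71 ± 0.27). Under quantile normalization the difference moved from -9.59 to -8.13 for Igf2 and from 0.99 to 1.73 for Fgfr3. The list was lower by camera in limma with a Benjamini-Hochberg adjusted p of 0.000709, and adjusted p = 0.256 with an estimated correlation. Of 29 glycolysis and hypoxia genes, 17 were lower, 3 higher and 9 neither (camera adjusted p 0.147, limma with Benjamini-Hochberg), and the list was called lower under quantile normalization (median -0.21, with 5 genes higher and 12 lower) and cyclic loess (-0.46). Under median scaling 7 were higher and 10 lower. Aldoa was 1.56-fold and Pkm 1.33-fold higher in rib tissue, and both calls were lost under quantile normalization (-0.41 and -0.16), median scaling (-0.35 and -0.12) and without RCS cells replicate 3 (-0.54 and -0.33), that of Aldoa also without rib tissue replicate 2 (-0.67) and that of Pkm without rib tissue replicate 1 (-0.36) or 3 (-0.36).

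Hox genes, which mark position along the body, differed in both directions. Of 27, 13 were higher in RCS cells, 9 lower and 5 neither, against 17 higher and 6 lower under quantile normalization (camera adjusted p 0.27, limma with Benjamini-Hochberg), with a list median of 0.54 that was -0.40 under the filter of 5 CPM. Hoxc8 (1.95 ± 0.28 against 8.50 ± 0.34) and Hoxc6 (4.09 ± 0.06 against 8.78 ± 0.13, 25.7-fold) were higher in rib tissue, and the difference of Hoxc6 moved from -4.68 to -3.86 under quantile normalization. Hoxb13 (7.14 ± 0.10) and Hoxc10 (5.68 ± 0.11) were listed at 0 in every rib library, and Hoxa13 was at 3.997 ± 0.12 against 0.45 ± 0.78.

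**Figure D2:**
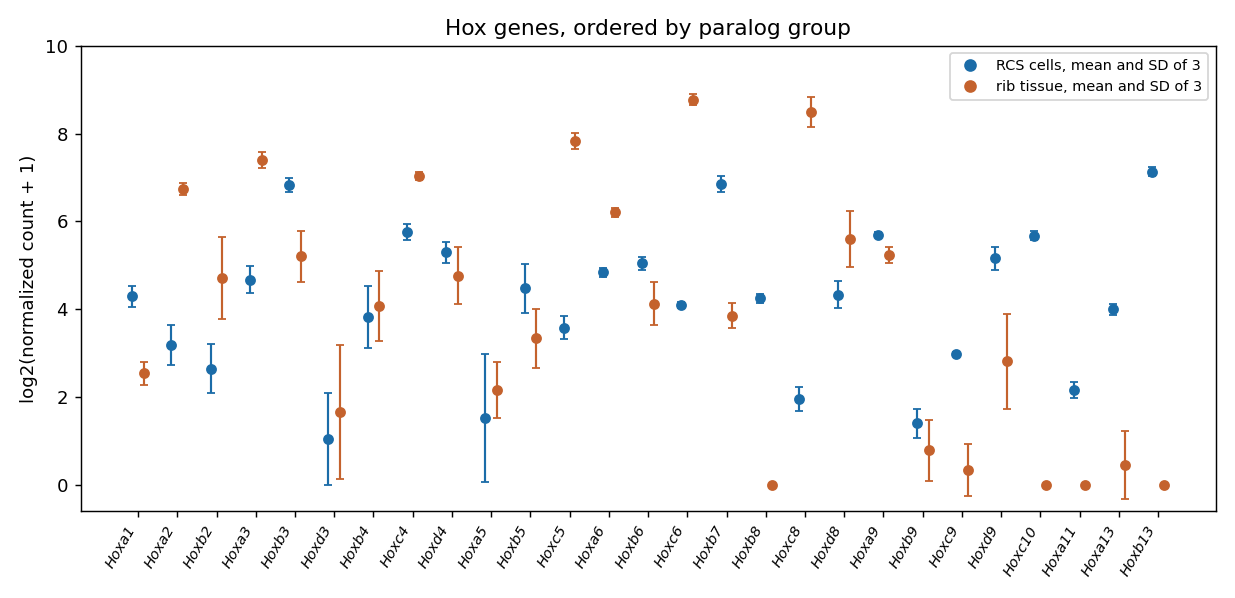
Levels of the Hox genes tested, ordered by paralog group, as log2(normalized count + 1), with points and bars for the mean and SD of 3 libraries in RCS cells (blue) and rib tissue (orange). Hoxc8 stands at 8.50 in rib tissue and Hoxb13 at 7.14 in RCS cells.

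Adjusted over the list alone, the lists other than the SOX and cartilage matrix lists gave the same counts as over all genes. The filter of 5 CPM left fewer members to test, with 5 of 7 erythroid, 6 of 8 osteoclast and 8 of 9 adipocyte genes lower, 2 higher and 1 lower of 3 lymphoid genes, and 7 higher and 8 lower of 16 Hox genes. Camera called 10 of 20 lists, 1 higher and 9 lower in RCS cells, 0 with an estimated correlation in limma (2 at an unadjusted p under 0.05) and 20 with fry, which asks only whether the genes of a list move one way on balance. In the plot of differences by list, the muscle genes all lie below 0 and the cell cycle genes all above.

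**Figure D3:**
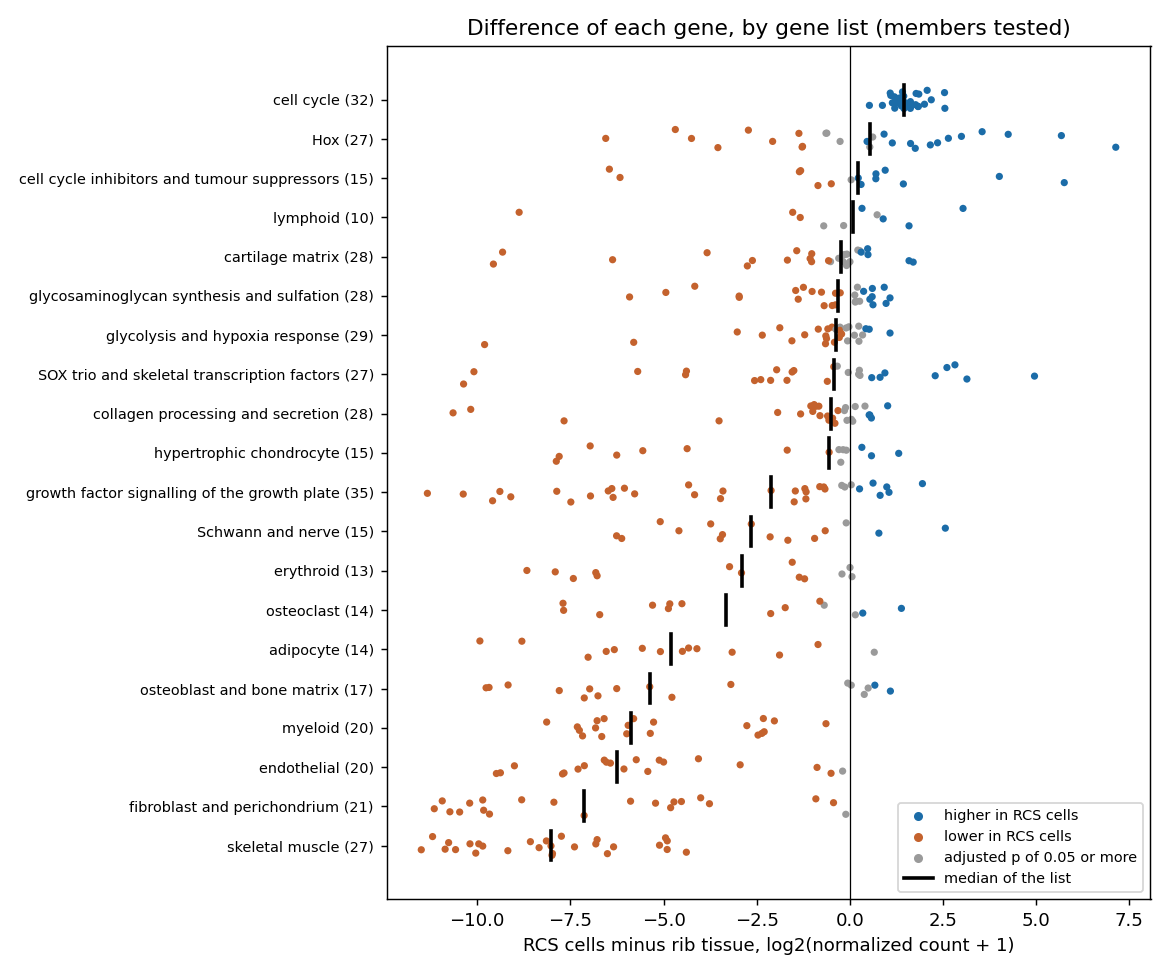
Difference of each gene (RCS cells minus rib tissue, log2(normalized count + 1)) in the 20 gene lists, with 1 point per gene, colour for the call and a black bar for the median of the list. The medians run from -8.02 for skeletal muscle to 1.45 for cell cycle genes.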

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

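Cyclic loess normalization, voom weights and the log2 values as deposited were chosen after the data were seen. More genes were higher in rib tissue than in RCS cells as reported, and more in RCS cells under quantile normalization, median scaling and cyclic loess. With the filter of 5 CPM and the scaling unchanged, 5077 were higher in RCS cells and 5094 in rib tissue. The excess in rib tissue therefore also depends on low genes. Counts at least 2-fold higher were 4880 (RCS cells, quantile normalization), 3622 (RCS cells, median scaling), 3506 (rib tissue, quantile normalization) and 3418 (rib tissue, filter of 5 CPM, where only 13075 genes were tested). Leaving out each library gave 4905 to 5540 genes higher in RCS cells, 6856 to 7306 in rib tissue, 2316 to 2382 and 5487 to 5596 at least 2-fold, and 8 to 11 lists. The lists called were 0 with an estimated correlation and 20 with fry. Differences that changed sign were, under quantile normalization, Col9a1 1.57, Hapln1 1.04, Wwp2 0.52, Sgms2 0.11 and Pmp22 0.068, and under median scaling Col9a1 0.10, Hapln1 0.25, Wwp2 0.25, Sgms2 0.11, Pmp22 0.19 and Vwf 0.098. Under cyclic loess they were Col9a1 0.68, Hapln1 0.45, Wwp2 0.18, Sp7 -0.13 and Tmcc2 -0.20, and with array weights Col9a1 0.0053, Hapln1 0.077, Wwp2 0.11, Sp7 -0.073 and Tmcc2 -0.015. Voom weights gave Tmcc2 -0.021. Over the fits without 1 library, differences ran from -0.36 to 0.023 for Col9a1, -0.17 to 0.15 for Hapln1, -0.23 to 0.11 for Wwp2, -0.17 to 0.20 for Tmcc2 and -0.28 to 0.30 for Sp7, with the ends that crossed 0 reached without rib tissue replicate 3. None of these genes was called as reported, and Col9a1 and Hapln1 (quantile, cyclic loess) and Wwp2 (quantile) were called higher in RCS cells. The direction of the list test turned, without a call, for cell cycle inhibitors (quantile, median 0.271), Hox genes (5 CPM, -0.404) and glycosaminoglycan genes (array weights, -0.237, and without rib tissue replicate 3, within medians of -0.362 to -0.218 over the fits without 1 library). The cause was not tested. Same-numbered libraries deviated together at r of 0.0638, -0.0764 and 0.047, so the numbers were not taken to pair the samples, and not every library deviated most closely with its own number. With the replicate number as a block 5536 and 7340 genes were higher in RCS cells and rib tissue, 2387 and 5608 at least 2-fold, and 11 lists were called, the osteoclast list being the added one, with no other call of a list or named gene changed. The depth of 5320000 to 8520000 reads limits what is known of genes listed at 0.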

Other observations

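All tests of explanations in this part were chosen after the result was seen, and the Hox groups compared were set then too. The main counts of genes and lists, quantile normalization and median scaling, which some of them draw on, were planned.

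RCS cells also held transcripts of genes outside the skeletal lists. Sox2, a factor of stem and neural cells, was at 7.95 ± 0.09 in RCS cells and 2.22 ± 0.22 in rib tissue. Among the Hox genes, Hoxb8 (4.25 ± 0.10) and Hoxa11 (2.16 ± 0.18) were listed at 0 in every rib library, and Hoxb7 was at 6.85 ± 0.18 against 3.85 ± 0.29. Other skeletal factors higher in RCS cells were Shox2 (9.01 ± 0.06 against 4.06 ± 0.33), Barx1 (6.51 ± 0.44 against 3.37 ± 1.19) and Nkx3-2 (8.96 ± 0.07 against 6.35 ± 0.35). The difference of Barx1 was 3.14, and 2.46 without rib tissue replicate 3, 4.58 under quantile normalization and 3.96 under cyclic loess. Under quantile normalization that of Hoxb7 moved from 2.99 to 4.45 and that of Shox2 from 4.95 to 6.32. These genes were chosen after their values were seen, and all of them passed the limma test.

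Of 14 Hox genes of paralog groups 9 to 13 in the table, 8 were tested, 7 higher in RCS cells and 0 lower, and of 22 of groups 1 to 8, 19 were tested, 6 higher and 9 lower, while a second Hoxa9 entry outside the list was lower in RCS cells (1.23 against 3.25). In rib tissue Hoxc10, Hoxa11 and Hoxb13 were listed at 0 and Hoxa13 (0.45) and Hoxc9 (0.34) stood near 0. These passed the filter through RCS cells and could not come out lower, so the filter shaped the split of groups 9 to 13. Reads shared with other group 13 genes are argued against for Hoxb13, which lay 3.14 log2 above the next of them in RCS cells. The scaling alternatives could not test library scaling, since 0 of the 3 lowered the median difference of the 7 and so none could end these calls. They moved the median gene by at most 0.53, while Hoxc9 (2.64), Hoxd9 (2.35), Hoxc10 (5.68), Hoxa11 (2.16), Hoxa13 (3.55) and Hoxb13 (7.14) differed by more. This argues against a factor per library as the source of the calls of these genes. Cyclic loess, which does not apply 1 factor to a library, moved Hoxc9 to 4.96, Hoxa11 to 4.67 and Hoxa13 to 5.65. These shifts are far above that of the median gene. A scaling effect that changes with the level of a gene was therefore not tested and stays open. For Hoxa9 (0.46) scaling cannot be told apart from a difference between the samples. The body position of the cells that the line came from and a change of Hox expression in the tumour or in culture stay open, and no biological explanation was tested.

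Cartilage matrix genes moved apart, 12 lower and 5 higher in RCS cells and 11 of 28 neither, where 76.5% of all tested genes were called. At least 2-fold, 11 were lower and 2 higher, against 5571 and 2369 of 16809 over all genes. Calls were thus no more frequent in this list than over all genes. Dilution of cartilage RNA by rib cells that do not express the members could only make them higher in RCS cells. The 12 lower members argue against such dilution as the whole cause. Whether other cells of the rib pieces express some of the lower members was not tested, so mixed tissue stays open. A factor per library moves all members by about the same amount. The differences ran from -9.57 (Cytl1) to 1.70 (Matn1), which argues against such a factor as the whole cause. Under quantile normalization 9 members were lower and 14 higher. That setting moved the median gene by 0.53, far less than the largest differences, so this count could not decide the question. Dilution as part of the pattern, the stage of the chondrocytes and loss of expression in culture stay open as untested.

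Abundant genes were lower in the shallowest library of each group, RCS cells replicate 3 and rib tissue replicate 2. Genes above 12 were higher in the deeper library in 4 of 6 pairs and lower in 1. The median was 0.38 (95% bootstrap interval 0.34 to 0.46) between RCS cells replicates 1 and 3. This interval was taken over 19 genes and does not measure the spread between replicates. The 6 pairs are not independent, since all 4 hold RCS cells replicate 3 or rib tissue replicate 2. In the pair that went the other way, RCS cells replicates 2 and 1, depth hardly differed (8520000 and 8310000 reads). Compression of abundant genes in shallower libraries cannot be told apart from a difference between the samples, since the pairs share libraries and went both ways. Of the 91 genes above 12 in any of these pairs, 82 were called as reported and 87 after cyclic loess normalization. Of the 82, 81 kept call and direction. A rib pair held 67 to 74 such genes and an RCS pair 18 to 21, so many entered through their level in rib tissue. Large differences that follow from this choice would outlast the removal of a trend of this size. The count therefore cannot decide whether the trend made calls. The sizes moved (Col2a1 -2.62 to -1.51, Acan 0.26 to 1.07 and newly called, Col9a1 -0.19 to 0.68), so the effect of the trend on them stays open.

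With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real grouping gave 5536 genes higher in RCS cells, 7324 in rib tissue, and 2369 and 5571 at least 2-fold, with 0 in limma as the highest of the other splits for each (185 genes at an unadjusted p under 0.05) and so 1 split as large, the real one. For gene lists the real grouping gave 10 and the highest other split 12, and 6 of the 10 splits gave as many. Every other split holds RCS and rib libraries on both sides. The difference between the groups then adds to the spread within each side, which keeps genes from being called. Part of it also stays between the sides, where camera can call lists by it. These splits therefore cannot decide whether the counts of genes or of lists arise by chance.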
